A study of Mus musculus with 6 samples.

How the data were processed

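Single-cell RNA sequencing was carried out on bone marrow cells of 3 wild-type (WT) and 3 Txnip knock-out (Txnip-KO) mouse samples. Per the labels' protocols, marrow was flushed from the bones, passed through a 70 µm strainer, enriched and sorted by fluorescence-activated cell sorting. The sorted population is not named in the labels. Libraries were made with the Chromium Single Cell 3' reagent kit version 3.1, which reads the 3' end of each transcript and tags each molecule with a unique molecular identifier (UMI). Each sample's group and replicate number were taken from its title. The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these 6 samples, which may in part be technical.

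The deposited files of each sample hold UMI counts per gene and cell barcode, without normalization, made with Cell Ranger 6.1.1 per the submitters' processing notes. These notes also name CASAVA 1.8 and Seurat 2.3.4. The genome build and annotation are not given in the sources used here. The files list 31253 features with an Ensembl identifier and a symbol, and 31107 of these identifiers were found in GENCODE release M21 (mouse build GRCm38), 30203 of them with the same symbol. Chromosome positions were taken from that annotation and are on GRCm38. Values of features that share a symbol (43 such symbols) were kept apart by identifier.

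The 6 samples hold 48277 barcodes and 445556425 UMIs. Barcodes with under 500 genes, under 1000 UMIs or over 10% mitochondrially encoded UMIs were left out, which kept 44399. Doublets were scored with Scrublet in scanpy 1.11.5, and in each sample the highest-scoring share was removed, set at 0.8% per 1000 barcodes, which took out 2886 barcodes (6.50%). Scrublet's own threshold would have marked 1469. The 41513 kept cells hold 389516215 UMIs. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were used, and cells were joined to 15 neighbours and grouped with the Leiden method at resolution 1, which gave 30 clusters. CPM stands for counts scaled to the same total in each sample. A cluster was named "X-like" where at least 3 markers and 50% of the markers of that cell type had a log2 fold of at least 1 over the other cells (10 CPM added), with a lead of 10 percentage points over the next list, and where its 10 leading genes did not go against the name. The markers were fixed before the data were examined, and these thresholds after. They named 22 clusters in 13 classes and left 8 clusters unnamed, which hold 29.0% ± 1.58 of WT and 21.6% ± 3.16 of Txnip-KO kept cells (SD, n = 3). Clusters of one name were joined, and the 17 classes with at least 20 kept cells in every sample were compared. Where different clusters hold much of a class in the 2 groups, their shares are given beside its values.

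Counts were summed per sample over all kept cells and per class, since cells are not replicates. The sums were tested with edgeR 4.0.16 (R 4.3.3): low genes removed with filterByExpr, TMM scaling, the quasi-likelihood test, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Log2 fold changes are Txnip-KO over WT and CPM of named genes are TMM-scaled, except those of Txnip and of markers read as background, which are scaled by total UMIs. Of 34 gene lists and 26 marker lists fixed before the data were examined, those with at least 3 tested genes (34 and 25) were tested with limma 3.58.1's camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. The number of kept cells per class was tested with the edgeR quasi-likelihood test, with the total of kept cells as library size. For the share of cells with a Txnip UMI and for cell cycle phase, each cell was thinned to 1000 UMIs, which left out 0 cells. Phase calls used 43 S and 52 G2M genes. These shares were compared with a two-sided exact permutation test, which cannot go below 0.1 with 3 samples against 3. The difference of the genotype effect between classes was tested with the interaction of class and genotype, with the sample as a block, each class against the class with the most kept cells, NK or innate lymphoid-like. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.

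The named genes followed a rule fixed before the data were examined: Txnip, then the 12 largest rises and 12 largest falls over all kept cells (5 and 5 per class) among genes past the threshold with a mean of at least 10 CPM and every Txnip-KO sample on the same side of every WT sample, without predicted genes. In lists, the members with the smallest p were named. The alternatives tried were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, the replicate number as a block, each replicate left out, no doublet removal, a stricter cell filter (1000 genes, 2000 UMIs, 5% mitochondrial), every deposited barcode, the same number of cells of each class (4369 cells per sample), Leiden resolutions 0.5 and 2, and genes centred per sample before clustering. Cells called G1, each cell thinned to 1000 UMIs before the sums, clustering without the changed genes, and single clusters of a class were added after the data were seen.

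The tests of genes, lists, class shares and the interaction were tried on simulated counts. Cluster naming, phase calls, thinning and the permutation, chi-square and correlation tests were not. Over all kept cells (14495 genes, 200 changed) edgeR recovered 62.7% of genes changed by a log2 fold of 0.5 and 100% of those changed by 1 or 2, with 15 false calls. In the HSC-like class (11270 genes) it recovered 70.1% at 0.5 and 100% at 1 and 2 with 11 false calls, and in the smaller T cell-like class (4892 genes) 11.5%, 48.3% and 98.3% at 0.5, 1 and 2 with 6 false calls. Over all kept cells, with no gene changed, 1 of 14507 genes was called. A list of 30 genes shifted by 0.5 was recovered in 10 of 10 simulations, and 0 of 90 unshifted lists were called, by camera with either correlation. Genes were drawn independently of one another, so this did not test false calls of lists whose genes move together. On the real counts, splits of the 6 samples that mixed the groups gave 5 to 14 called lists by camera at the preset correlation. Shares changed by a log2 fold of 1 were recovered in 100% of cases and 1.69% of unchanged classes were called. These shares were simulated with the same set spread between samples for every class, and only the larger classes were counted. The real spread was wider in some classes (basophil or mast-like 6.01% ± 3.62 in Txnip-KO), so recovery in those classes was not tested. For the interaction, tested for the HSC-like class (11734 genes), 81.0% of differences of 1 were recovered with 11 false calls. Replicates of a group differed by more than counting noise (chi-square over degrees of freedom 10.7 to 16.9 in WT and 56.3 to 90.8 in Txnip-KO), so none was counted as a repeat of another. Read-level data were not used here.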

Results

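The transcriptomes of single, sorted bone marrow cells were compared between 3 WT and 3 Txnip-KO mouse samples. The deposited counts hold 7213, 8140 and 8097 barcodes with 72152212, 80876483 and 79840940 UMIs in WT 1, 2 and 3, and 6973, 9063 and 8791 barcodes with 61368478, 80688688 and 70629624 UMIs in Txnip-KO 1, 2 and 3. After filtering, 6190, 7020 and 6798 WT cells and 6023, 7827 and 7655 Txnip-KO cells remained. The median UMIs per kept cell was 9017 ± 156 in WT and 7653 ± 646 in Txnip-KO (mean of sample medians ± SD, n = 3 each), so the Txnip-KO cells held fewer UMIs. The marrow held stem and progenitor cells (HSC-like, granulocyte-monocyte progenitor-like, megakaryocyte lineage-like and erythroid lineage-like), NK or innate lymphoid-like, T cell-like and B-lineage-like cells, basophil or mast-like, neutrophil-like and monocyte-like cells, plasmacytoid dendritic cell-like cells, and small stromal-like and plasma cell-like clusters. Of the unnamed clusters, cluster 7 was led by Flt3, Dntt and Il12a, cluster 8 by Dntt, Ebf1 and Rag1. Cluster 21 was led by Fn1, Cd74 and S100a4, cluster 17 by Cxcr6, Gata3 and Icos, cluster 20 by Rora, Tox2 and Tcf7, and clusters 3, 11 and 12 by genes of the dividing cell.

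Txnip encodes thioredoxin-interacting protein, an arrestin-family protein that binds thioredoxin and limits glucose uptake. The gene (ENSMUSG00000038393) lies on chromosome 3 from 96557957 to 96561883 on the plus strand of GRCm38. Txnip stood at 306, 209 and 270 CPM in WT 1, 2 and 3 (261 ± 49.1) and at 10.8, 9.55 and 0.459 in Txnip-KO 1, 2 and 3 (6.93 ± 5.64). These are 19619, 14918 and 18695 Txnip UMIs against 584, 662 and 28. The fall was -5.35 on the log2 scale (SE 0.80; adjusted p = 0.00232, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Txnip fell in all 17 classes, from -2.70 in neutrophil-like cells to -7.97 in cluster 20. In neutrophil-like cells the fall was not called by the DESeq2 Wald test (-3.02, adjusted p = 0.138), and the value of cluster 20 rests on 1 UMI in Txnip-KO 1 and 0 in Txnip-KO 2 and 3. With each cell thinned to 1000 UMIs, 27.9% ± 4.18 of WT and 0.894% ± 0.711 of Txnip-KO cells held a Txnip UMI (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 can give). Unthinned, 5076 of 6190, 5269 of 7020 and 5476 of 6798 WT cells and 513 of 6023, 576 of 7827 and 27 of 7655 Txnip-KO cells held a Txnip UMI. The labels do not say which part of the gene was deleted, and 3' counts outside that part would not test the deletion. The predicted gene Gm15441 lies over Txnip on the opposite strand (96555765 to 96566801) and, chosen after its values were seen, had a log2 fold change of 1.72 (SE 0.62; adjusted p = 0.0544 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Whether the counting used strand is not given in the sources used here.

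**Figure D1:**
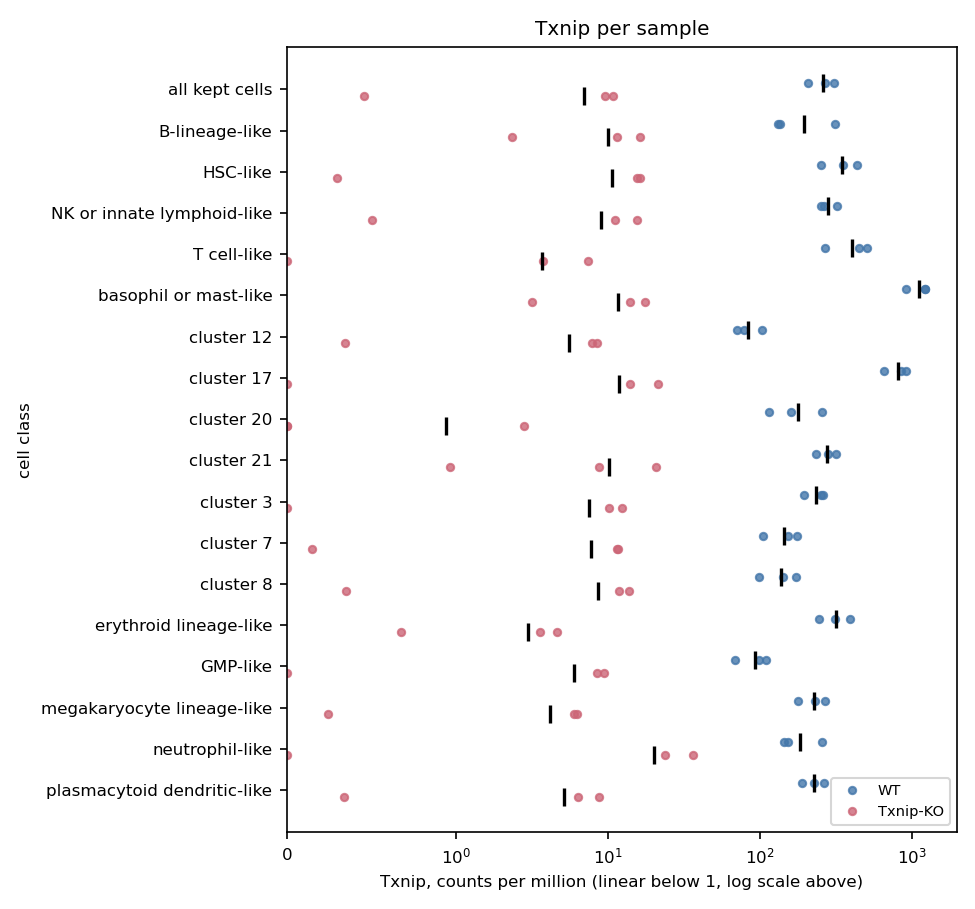
Txnip in each sample, in CPM (x axis, linear below 1 and on a log scale above), over all kept cells and in each of 17 cell classes (y axis). Points are samples (3 WT in blue, 3 Txnip-KO in red) and black bars are group means, with over all kept cells 261 in WT and 6.93 in Txnip-KO.

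The series asks how these cells differ between WT and Txnip-KO. Over all kept cells, the closest relative of Txnip in the arrestin family, Arrdc4, rose from 10.2 ± 1.76 to 46.6 ± 2.04 CPM (log2 fold change 2.19, SE 0.12, n = 3 against 3). The Krüppel-like factor Klf10 rose from 18.3 to 64.1 CPM (1.81, SE 0.11), the acyl-CoA thioesterase Acot1 from 11.8 to 49.9 (2.08, SE 0.17), and Ddit4, an inhibitor of mTORC1 signalling, from 14.99 to 45.8 (1.61, SE 0.27). Oxct1, which allows ketone bodies to be used as fuel, fell from 83.9 ± 7.07 to 20.6 ± 2.21 CPM (-2.03, SE 0.10), and Lars2, the mitochondrial leucyl-tRNA synthetase, from 495 ± 69.5 to 111 ± 31.7 (-2.15, SE 0.20). Idi1 and Fdps, enzymes of the mevalonate pathway, fell from 41.7 to 12.6 CPM (-1.73, SE 0.14) and from 63.6 to 19.4 CPM (-1.71, SE 0.17).

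Other rises were those of Polr3gl, a subunit of RNA polymerase III (33.5 to 127 CPM, 1.92), Tmem158 (7.89 to 23.7, 1.59) and the histone gene H2ac6 (13.1 to 39.1, 1.57), whose near-identical copies make its count uncertain. The light chain Igkc (51.5 to 1064 ± 1679 CPM, 4.37), Iglc2 (6.76 to 23.2, 1.78), the neutrophil product Retnlg (3.98 to 136 ± 168, 5.09), the stromal chemokine Cxcl12 (5.89 to 38.6, 2.71) and the globin gene Hbb-bt (17.8 to 75.9, 2.09) also rose. In the same samples the neutrophil-like share was 0.492% in WT and 2.07% in Txnip-KO, the stromal-like share 0.0603% and 0.238%, and all 34 plasma cell-like cells came from Txnip-KO 2. Falls among genes that mark a class were those of the basophil proteases Mcpt8 (557 to 88.3 CPM, -2.66) and Prss34 (617 to 166, -1.90) and the IgE receptor chain Fcer1a (-1.93). Also lower were the recombinase Rag1 (21.7 to 4.27, -2.34), neutrophil elastase Elane (70.1 to 19.1, -1.88), Upb1 (-1.88), the lymphocyte chemokine Xcl1 (66.1 to 19.7, -1.74) and Myl4 (26.4 to 7.99, -1.72). The basophil or mast-like share was 12.1% in WT and 6.01% in Txnip-KO beside them, and the plasmacytoid dendritic cell-like share, whose cluster 19 Upb1 marks, 8.79% and 4.91%. Rag1 and Myl4 mark cluster 8 and Xcl1 cluster 13, so cell numbers may add to their falls. With the same number of cells of each class, Rag1 in all kept cells was at -1.79, Elane in all kept cells at -2.005, Upb1 in all kept cells at -1.15, Xcl1 in all kept cells at -1.92 and Myl4 in all kept cells at -1.52, all still called by the edgeR quasi-likelihood test. Igkc in all kept cells lost its call without WT 1, 2 or 3 (4.39, 4.23 and 4.49) and was at 0.65 without doublet removal. Iglc2 in all kept cells lost its call without WT 1, 2 or 3 (1.75, 1.74 and 1.83) and without doublet removal (1.10). Cxcl12 in all kept cells was at 0.62 and not called with the same number of cells of each class. Fcer1a in all kept cells lost its call without WT 2 (-1.71), and Prss34 in all kept cells without WT 2 (-1.69) or Txnip-KO 3 (-1.68).

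**Figure D2:**
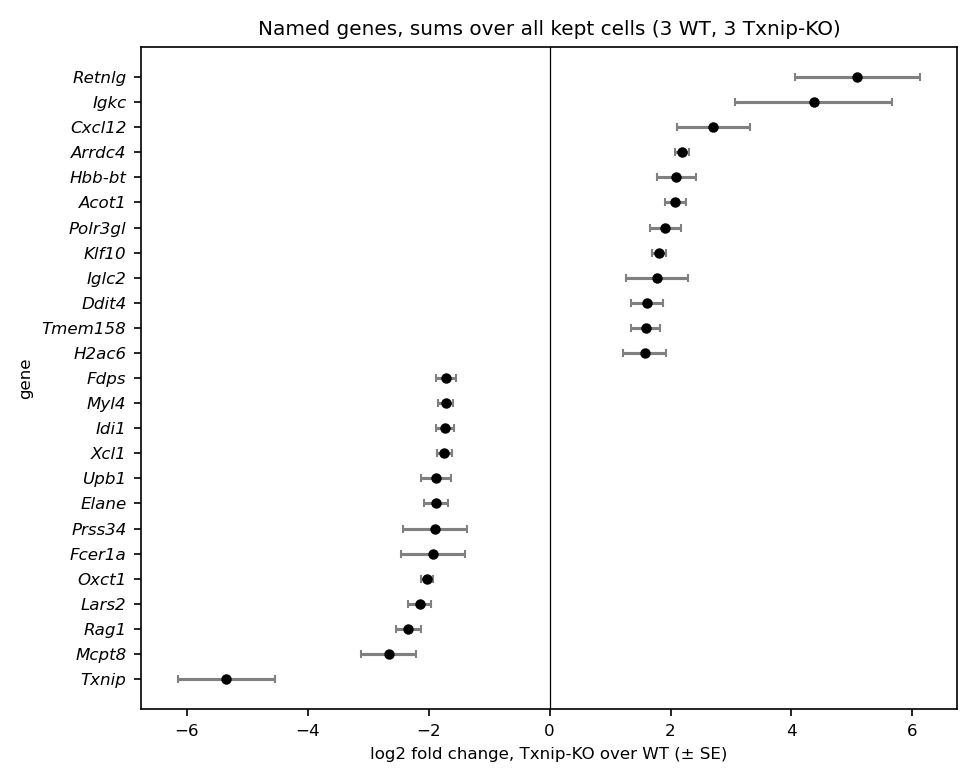
Log2 fold change, Txnip-KO over WT (x axis, bars ± SE, n = 3 against 3), of Txnip and the 24 named genes (y axis) over all kept cells. Arrdc4 (2.19), Klf10 (1.81) and Oxct1 (-2.03) have short error bars, and Igkc (4.37) and Retnlg (5.09) long ones.

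Of 14651 genes tested over all kept cells, 3170 were higher and 2840 lower in Txnip-KO (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05), 6010 in all. The named genes have adjusted p from 0.000111 (Oxct1) to 0.0278 (Igkc) by this edgeR test with Benjamini-Hochberg adjustment. The count dropped to 3609 without WT 2 and 3755 without WT 3, and was 2647 with each cell thinned to 1000 UMIs. The balance turned to more lower than higher genes with DESeq2 size factors (2941 higher and 3067 lower), by the DESeq2 Wald test (2823 and 3177) and without the filter on low counts (2676 and 3154). It turned too without doublet removal (2952 and 3104), with every deposited barcode (2943 and 3095) and with the same number of cells of each class (3092 and 3326), so neither direction prevailed.

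Genes of oxidative phosphorylation encoded in the nucleus fell together: 69 of 75 tested members were lower and 0 higher (70 lower adjusted over the list alone), with a median of -0.43. Ndufa9 (-0.59), Ndufs8 (-0.65), Cox6a1 (-0.51) and the electron carrier Cycs (-0.71) led this list. Of the 13 mitochondrially encoded genes, 2 were higher and 3 lower over all genes tested (2 and 4 adjusted over the list alone), with mt-Co1 at 0.52 and mt-Atp8 at -0.56. Cholesterol synthesis had the largest median of the gene lists that were lower, -0.99, with 18 of 20 members lower and 0 higher (19 lower adjusted over the list alone), led by Cyp51 (-1.501), Mvk (-1.57), Idi1 (-1.73) and Msmo1 (-1.27). Cell cycle S genes were lower in 38 of 43 cases and higher in 0 (40 lower adjusted over the list alone, median -0.63), with Cdc45 (-1.07), Ccne2 (-1.11) and Tyms (-1.13) in front. G2M genes were lower in 42 of 52 and higher in 1 (42 and 1 adjusted over the list alone, median -0.59), with Ccnb2 (-0.87) and Birc5 (-1.02). Ribosome biogenesis and MYC targets had 22 of 31 lower and 0 higher (23 lower adjusted over the list alone). These include Eif4a1 (-0.65), Bop1 (-0.54) and Nme1 (-0.73). By limma's camera these lists had adjusted p of 5.58e-20 (oxidative phosphorylation), 1.05e-11 (cholesterol synthesis), 2.83e-16 (S), 1.24e-14 (G2M) and 2.25e-07 (ribosome biogenesis), and of 0.410 for the mitochondrially encoded genes. None of these calls held with camera's estimated correlation: adjusted p = 0.575 with an estimated correlation for each of the 5 called lists. Of the lists that mark cell types, neutrophil granule and haemoglobin genes were not called in the same samples, while 7 marker lists, given below, were.

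Stress and defence lists were lower too. Unfolded protein and ER stress genes were lower in 13 and higher in 3 of 24 cases (13 and 3 adjusted over the list alone), with Selenos (-0.88), Pdia3 (-0.58) and Sdf2l1 (-1.62) lower and Trib3 (1.43) higher. Heat shock genes were lower in 7 of 11 cases and higher in 0 (7 and 1 adjusted over the list alone), led by Dnaja1 (-0.63) and Hspe1 (-0.70). Interferon response genes were lower in 17 and higher in 1 of 37 cases (17 and 1 adjusted over the list alone), led by Ifi27l2a (-1.37) and Isg15 (-1.35). Of 21 thioredoxin and peroxiredoxin genes, 10 were lower and 1 higher (10 and 1 adjusted over the list alone), with Prdx1 (-0.62), Glrx3 (-0.54) and thioredoxin itself, Txn1 (-0.46), a binding partner of Txnip. Of 9 pentose phosphate genes 4 were lower and 0 higher (5 lower adjusted over the list alone), with Pgls (-0.57) and Tkt (-0.34). Of 18 cyclins and CDK inhibitors 8 were lower and 3 higher (9 and 3 adjusted over the list alone), with Ccna2 (-0.84), E2f1 (-0.79) and Ccne1 (-1.03). Of 78 ribosomal protein genes 9 were lower and 6 higher (3 and 5 adjusted over the list alone), with Rpl27 at -0.75 and Rpl38 at 0.36. By limma's camera the adjusted p was 0.00197 (unfolded protein), 0.0105 (heat shock), 0.000526 (interferon), 0.00248 (thioredoxin), 0.0105 (pentose phosphate), 0.0155 (cyclins) and 0.0119 (ribosomal protein). With an estimated correlation none held, with adjusted p = 0.907 with an estimated correlation for ribosomal protein and 0.575 for the other 6. Heat shock lost its call without WT 1 (adjusted p = 0.0555 by camera) and ribosomal protein without WT 3 (0.0712) or Txnip-KO 1 (0.113).

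FoxO targets, HSC maintenance genes and sex-linked genes were higher. FoxO targets were higher in 12 of 22 cases and lower in 0 (12 adjusted over the list alone). These were led by the insulin receptor Insr (0.78), the PI3-kinase inhibitor Pik3ip1 (1.30), Rictor (0.62) and Ccng2 (0.56). HSC maintenance genes were higher in 17 and lower in 1 of 32 cases (19 and 2 adjusted over the list alone), led by Hoxa5 (0.91), Hoxa10 (0.82), Fgd5 (1.497) and Procr (0.82). The HSC-like share of kept cells was 8.68% in WT and 14.2% in Txnip-KO beside them. Of 6 sex-linked genes 5 were higher and 0 lower (5 adjusted over the list alone): the Y-linked Uty (0.51), Ddx3y (0.46) and Kdm5d (0.29), and Tsix (1.70). By limma's camera the adjusted p was 0.0105 (FoxO), 0.00031 (HSC maintenance) and 0.0115 (sex-linked). The same test gave adjusted p = 0.575 with an estimated correlation for each of the 3. Among cells called G1, an alternative chosen after the data were seen, FoxO targets lost their call by limma's camera (adjusted p = 0.112), as did pentose phosphate (0.0818), G2M (0.0855), cyclins (0.265) and ribosomal protein genes (0.0541). In all, camera called 15 of 34 lists (3 higher and 12 lower) and fry called 19 as moving on balance one way, while camera with an estimated correlation called 0, with 0 at an unadjusted p under 0.05.

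The other 19 lists were not called by camera, with adjusted p of at least 0.145. Of these, antigen presentation class II was called higher by camera with the same number of cells of each class (adjusted p = 0.0194). Autophagy and lysosome genes were called lower by camera among cells called G1 (adjusted p = 0.0421). The MondoA and ChREBP list had 5 of 14 members higher and 4 lower (6 and 5 adjusted over the list alone), and its leading members were Arrdc4 (2.19), Klf10 (1.81), Pfkfb3 (0.87) and Klf11 (1.91). Glucose uptake and glycolysis genes were higher in 6 and lower in 9 of 27 cases (7 and 9 adjusted over the list alone), with Pfkfb3 at 0.87 and hexokinase Hk2 at -1.26. Of the Txnip and arrestin family, Arrdc4 and Arrb1 (0.31) were higher and Txnip lower among 7 genes (2 and 1 adjusted over the list alone). Fatty acid oxidation had 4 higher and 5 lower of 21 (4 and 5 adjusted over the list alone), with Cpt1a at 1.05 and Slc25a20 at 0.81. Counts higher and lower were 5 and 8 of 32 for glutathione and NRF2 targets, 6 and 8 of 29 for p53 targets, and 7 and 3 of 20 for homing and adhesion. They were 4 and 2 of 28 for NF-kB, 1 and 0 of 10 for antigen presentation class II and 2 and 0 of 12 for class I. Those counts were 5 and 7 of 25 for mTORC1 and amino acid response, 4 and 7 of 20 for hypoxia, and 4 and 10 of 28 for autophagy. They were 4 and 7 of 22 for apoptosis regulators, 5 and 2 of 24 for immediate early genes, 5 and 5 of 16 for haemoglobin and haem synthesis, and 6 and 3 of 16 for neutrophil granule genes. The same counts adjusted over the list alone were 6 and 8 (glutathione), 7 and 8 (p53), 8 and 3 (homing), 3 and 1 (NF-kB), 0 and 0 (class II), 2 and 0 (class I), and 5 and 7 (mTORC1). They were 4 and 7 (hypoxia), 5 and 10 (autophagy), 4 and 7 (apoptosis), 4 and 1 (immediate early), 5 and 5 (haemoglobin) and 7 and 3 (neutrophil granule). Median, mean and test differed in sign for the Txnip and arrestin family (median 0.21, mean -0.31), glutathione, fatty acid oxidation, NF-kB, class I, mTORC1 and haemoglobin.

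Among the marker lists, stromal markers were higher in 11 of 11 cases (11 adjusted over the list alone; median 2.34), HSC markers in 10 of 14 (10) and multipotent progenitor markers in 5 of 10 with 1 lower (7 and 1). Granulocyte-monocyte progenitor markers were lower in 9 of 12 cases (10 adjusted over the list alone), led by Elane (-1.88), Clec12a (-0.89) and Ctsg (-0.86). The granulocyte-monocyte progenitor-like share of kept cells was 5.89% in WT and 8.07% in Txnip-KO beside them (log2 fold change 0.45, not called; 0.21 with changed genes left out of the clustering). At resolution 2 that share was called lower (-0.70). With genes centred per sample, cells of this name numbered 140, 178 and 155 in WT 1, 2 and 3 and 102, 699 and 557 in Txnip-KO 1, 2 and 3. Lower too were 7 of 12 monocyte markers, 7 of 11 plasmacytoid dendritic cell markers and 7 of 12 B-lineage markers (7 each adjusted over the list alone), among them Csf1r (-0.71), Bst2 (-1.07) and Vpreb1 (-1.42). By limma's camera these 7 lists had adjusted p of 0.000144 (stromal), 0.000784 (HSC), 0.0320 (multipotent), 0.000784 (granulocyte-monocyte), 0.0119 (monocyte), 0.00379 (plasmacytoid dendritic) and 0.00173 (B-lineage). With an estimated correlation 0 of the 25 marker lists were called (1 at an unadjusted p under 0.05, 4 by fry), with adjusted p = 0.555 with an estimated correlation the lowest. The other 18 marker lists had adjusted p of at least 0.0909 by camera.

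**Figure D3:**
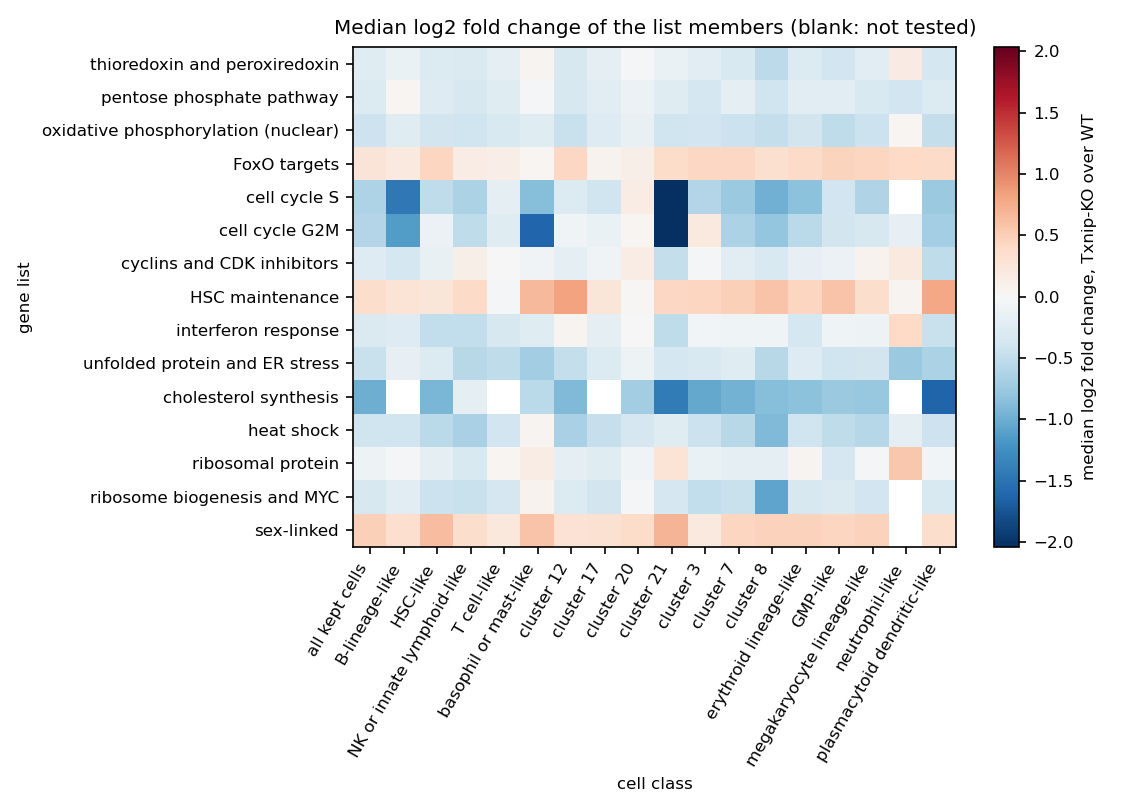
Median log2 fold change, Txnip-KO over WT (colour scale), of the members of the 15 lists that camera called over all kept cells (y axis), over all kept cells and in each class (x axis); blank squares were not tested. Cholesterol synthesis is blue in each of the 13 classes where it was tested, with medians from -1.62 to -0.20.

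The same lists were tested within each class. Oxidative phosphorylation genes were lower by limma's camera in 16 of 17 classes, heat shock genes in 15 of 17, unfolded protein genes in 14 of 17, S genes in 14 of 16, ribosome biogenesis genes in 14 of 16 and cholesterol synthesis genes in 12 of 13. Camera with an estimated correlation called 0 of these or any other tests of a list in a class, with 51 at an unadjusted p under 0.05 and adjusted p = 0.0510 with an estimated correlation the lowest. HSC maintenance genes were higher in 11 of 17 classes, FoxO targets in 9 of 17 and the MondoA and ChREBP list, which was not called over all kept cells, in 6 of 16. Ribosomal protein genes were lower in 9 and higher in 5 of 17, and these calls too were lost with an estimated correlation. Of 559 tests of a list in a class, camera called 199 and fry 207.

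Near Txnip on chromosome 3, 7 of 24 tested neighbours were higher and 4 lower over all genes tested (7 and 5 adjusted over the list alone). Polr3gl, 15989 bp away on the opposite strand (96577872 to 96594181), had the largest change among these 24 genes (1.92, SE 0.25). Lix1l (0.98), Prkab2 (0.72), Sv2a (0.59), Otud7b (0.52) and Bcl9 (0.27) were also higher, and Sf3b4 (-0.54), Anp32e (-0.36), Notch2 (-0.27) and Gpr89 (-0.25) lower. As a list they were not called by limma's camera (adjusted p = 0.683; 0.907 with an estimated correlation).

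Within HSC-like cells, the sulfotransferase Sult1a1 (log2 fold change 2.29, SE 0.33), Arrdc4 (2.17, SE 0.15), Klf11 (1.97, SE 0.20), Tmem158 (1.94) and Polr3gl (1.87) rose. Lars2 (-2.19, SE 0.13), Oxct1 (-2.12, SE 0.12), the RNA helicase Ddx4 (-1.93), the aldolase Aldoc (-1.85) and Sdf2l1 (-1.77) fell (n = 3 against 3). In all, 1824 genes were higher and 2069 lower in these cells (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05). Without WT 2, 2517 changed, and at resolution 2 2373. Markers of other cells were read in HSC-like cells at 9.57 ± 3.48 CPM in WT and 16.7 ± 10.97 in Txnip-KO for S100a8, and at 3.85 ± 2.03 and 18.8 ± 18.7 for Igkc (SD, n = 3).

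In granulocyte-monocyte progenitor-like cells Arrdc4 (2.58), Klf10 (1.97), the transcription factor Jun (2.07), Hbb-bt (2.35) and H2ac6 (1.89) rose, and Erdr1 (-3.41), Oxct1 (-2.34), Elane (562 to 136 CPM, -2.05), Ly6c2 (-1.86) and Lars2 (-1.70) fell. In these progenitors 2208 genes were higher and 2351 lower by the edgeR quasi-likelihood test, with 1754 changed at resolution 2. Hbb-bt also marks the HSC-like cluster. S100a8 and Igkc, markers of other cells, were read in these progenitors at 5.30 ± 1.03 and 3.85 ± 1.66 CPM in WT and 13.8 ± 10.9 and 19.8 ± 23.3 in Txnip-KO (SD, n = 3). The globin gene Hba-a1 stood at 0.836 ± 0.238 and 0.912 ± 0.598 CPM there, and background was not separated from expression for Hbb-bt. In cluster 7, Arrdc4 (3.42), Klf10 (2.12), Acot1 (2.09), Hbb-bt (2.32) and H2ac6 (1.85) rose. Erdr1 (-3.30), Oxct1 (-2.61), Lars2 (-2.02), Idi1 (-1.80) and Sdf2l1 (-1.74) fell. Cluster 7 had 2057 higher and 2252 lower genes. In cluster 8, Arrdc4 (4.11), Acot1 (3.33), Klf9 (3.30), the glutamate receptor subunit Gria2 (2.93) and the pro-apoptotic Bmf (2.56) rose. Oxct1 (-2.87), Pclaf (-2.71), the fatty acid-binding Fabp5 (-2.32) and the monocarboxylate transporter Slc16a1 (-2.28) fell. Cluster 8 had 1965 higher and 2160 lower genes.

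In erythroid lineage-like cells Slc28a2 (3.36), Gpr183 (2.93) and the alpha-globin genes Hba-a1 (4.16) and Hba-a2 (3.83) rose, while Lars2 (-2.17), Oxct1 (-1.71), Sdf2l1 (-1.57) and the histone chaperone Asf1b (-1.57) fell. Trnp1 stood at 0.0661 ± 0.0572 CPM in WT and 44.0 ± 47.8 in Txnip-KO. The globin rises turned without doublet removal (Hba-a1 -0.34 and Hba-a2 -0.24) and at resolution 0.5 (-0.38 and -0.35), and near-identical copies make both genes uncertain. In all, 1935 genes were higher and 2022 lower by the edgeR quasi-likelihood test. Without WT 2, 2290 changed, and without WT 3 2541. Cluster 5, led by division genes, held 21.2% of this class in WT and 13.01% in Txnip-KO, and cluster 0 the rest, with 910 and 3734 genes changed in these clusters by themselves. In megakaryocyte lineage-like cells Slc28a2 (2.54), the protease inhibitor Slpi (2.38), Polr3gl (2.06) and Tmem158 (1.93) rose. Erdr1 (-3.37), Mcpt8 (-2.50), Lars2 (-2.18), Sdf2l1 (-1.77) and Scin (-1.65) fell. Here 1575 genes were higher and 1697 lower. In these cells 2044 changed without WT 2, 2174 without WT 3 and 2050 with the stricter cell filter. Mcpt8 marks basophils, whose share was 12.1% in WT and 6.01% in Txnip-KO, and it was also read in HSC-like cells (12.1 ± 3.56 and 4.79 ± 2.99 CPM), and background was not separated from expression here.

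In plasmacytoid dendritic cell-like cells Acot1 (4.83), Lax1 (3.60), Klf10 (3.15), Bmf (3.08) and Slc4a8 (3.07) rose. Oxct1 (-3.11), argininosuccinate synthase Ass1 (-2.93), Cadm1 (-2.56), Fdps (-2.43) and squalene epoxidase Sqle (-2.28) fell. This class had 1810 higher and 1764 lower genes by the edgeR quasi-likelihood test. Cluster 19 held 80.6% of this class in WT and 56.1% in Txnip-KO, and cluster 23 the rest, with 2243 and 2517 genes changed in these clusters by themselves. In cluster 21, Sult1a1 (3.66), Klf9 (3.58), Fgfr1 (3.42) and the leukaemia inhibitory factor receptor Lifr (3.37) rose, Vmn2r26 went from 0.832 to 55.5 CPM (5.94), and Idi1 (-4.02), Elane (-3.98), Uhrf1 (-3.47), Cenph (-3.22) and thymidine kinase Tk1 (-3.13) fell. Cluster 21 had 1306 higher and 1403 lower genes, and 1757 changed at resolution 2.

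In NK or innate lymphoid-like cells Arrdc4 (3.16), the interleukin-7 receptor Il7r (49.7 to 210 CPM, 2.07), Pik3ip1 (2.02) and Klf10 (1.84) rose. Pclaf (-3.18), Lars2 (-2.49), Isg15 (-2.23), Xcl1 (-1.97) and Oxct1 (-1.92) fell. There, 1462 genes were higher and 1507 lower by the edgeR quasi-likelihood test (1758 changed without WT 3). Cluster 13 held 75.2% of this class in WT and 47.8% in Txnip-KO, cluster 14, led by Gzma and Prf1, 20.5% and 43.1%, and cluster 27 4.24% and 9.10%. In basophil or mast-like cells Cldn1 (4.76), Trnp1 (4.56), Acot1 (3.69), Gpr65 (3.56) and Filip1l (2.55) rose. H3c3 (-3.19), Ccna2 (-3.04), H2ac10 (-2.97), Ube2c (-2.93) and Rrm2 (-2.84) fell. In this class 780 genes were higher and 843 lower. Cluster 15 held 86.3% of that class in WT and 67.2% in Txnip-KO and cluster 16 10.1% and 32.3%. By themselves they had 841 and 561 changed genes, of which 527 and 313 were among the 1623 of the class, called in the same direction. Cluster 28, with H3c3 and H1f5 among its leading genes, held 3.56% and 0.434% (86 WT and 7 Txnip-KO cells), and the falls of division genes in the class were not separated from its lower number of cells. The basophil or mast-like count ran from 479 without WT 2 to 2527 without Txnip-KO 1, with 838, 962 and 828 without WT 1, WT 3 and Txnip-KO 2.

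Of the clusters led by cell division genes, cluster 12 had 1625 higher and 1817 lower genes by the edgeR quasi-likelihood test, with Arrdc4 (3.03), Acot1 (2.57), S100a9 (2.77), Hbb-bt (2.57) and Ccl4 (2.11) up and Erdr1 (-3.50), Ly6c2 (-2.96), Ly6d (-2.85), Cox6a2 (-2.32) and Atp1b1 (-2.14) down. Cluster 3 had 936 higher and 1086 lower (1292 and 1274 changed without WT 1 and WT 2, and 1127 by the DESeq2 Wald test), with Arrdc4 (2.42), Hbb-bt (2.49), Hist1h2ap (2.44), Acot1 (2.16) and H2ac6 (1.91) up and Ly6c2 (-1.96), Lars2 (-1.95), Insig1 (-1.79), Cox6a2 (-1.69) and Cyp51 (-1.66) down. S100a9 and Hbb-bt are markers of other cells.

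Fewer genes changed in the small classes by the edgeR quasi-likelihood test. B-lineage-like cells had 162 higher and 163 lower, with Klf10 (4.79), Nav2 (3.16), Wls (2.78), the cholesterol transporter Abca1 (2.26) and Snx29 (2.01) up and the replication genes Pclaf (-3.38), Lig1 (-3.02), Prim1 (-3.00) and Mcm5 (-2.81), with Spc25 (-2.93), down. Cluster 17 had 115 higher and 125 lower, with Polr3gl (2.38), Manba (2.297) and Arrdc4 (2.07) up and Ppa1 (-2.38), Lars2 (-2.24) and Cpa3 (-2.05) down. Cluster 20 had 57 higher and 29 lower, with Klf11 (3.20), Arrdc4 (3.08) and Klf9 (2.32) up and Lars2 (-2.33), Oxct1 (-2.13) and the pyruvate carrier Mpc1 (-1.08) down. In the T cell-like class, cluster 22 held 61.2% of cells in WT and 86.7% in Txnip-KO and cluster 24, led by Bcl11b, Themis and Rag1, 38.8% and 13.3%. Cluster 22 by itself had 239 changed genes. T cell-like cells as a class had 46 higher and 30 lower, with Arrdc4 (2.92), Arap3 (2.34) and Gpr183 (1.89) up and Iigp1 (-3.13), Cd8b1 (-2.83), the transcription factor Maf (-2.77) and Lars2 (-2.28) down. Neutrophil-like cells had 46 higher and 26 lower, with Ccl6 (30.2 to 711 CPM, 4.60), Asprv1 (4.11), Ly6e (3.44), Srgn (3.40) and Retnlg (2.84) up and Lars2 (-2.85), Dnajb14 (-1.74), Ero1l (-1.67), Srebf2 (-1.60) and Tnfsf13b (-1.51) down. Single libraries moved these counts. The T cell-like count was 19, 387 and 5 without WT 1, 2 and 3 and 2, 4 and 13 without Txnip-KO 1, 2 and 3. The neutrophil-like count was 38, 41 and 36 without WT 1, 2 and 3, and 42 and 154 without Txnip-KO 1 and 2. The B-lineage-like count was 171, 185 and 147 without WT 2, WT 3 and Txnip-KO 1. It was 3387 without doublet removal, 1144 and 1030 at resolutions 0.5 and 2, 531 with the stricter cell filter and 104 by the DESeq2 Wald test. The cluster 17 count was 53, 43 and 40 without WT 1, 2 and 3 and 98 without Txnip-KO 1, and the cluster 20 count 45, 25 and 28 without WT 1, 2 and 3 and 44 without Txnip-KO 2. Without the filter on low counts 247 genes changed in T cell-like cells, 397 in cluster 17, 253 in cluster 20 and 153 in neutrophil-like cells. Without doublet removal these counts were 244, 112, 204 and 150. With the replicate number as a block 14 changed in T cell-like cells, 143 in cluster 17 and 124 in neutrophil-like cells, and by the DESeq2 Wald test 138 in cluster 17 and 42 in neutrophil-like cells. At resolution 0.5, 465 changed in cluster 17.

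The share of cells called S or G2M, with each cell thinned to 1000 UMIs, was 49.1% ± 1.67 in WT and 39.7% ± 3.14 in Txnip-KO over all kept cells (SD, n = 3), a difference of -9.42 percentage points. In erythroid lineage-like cells the share was 74.8% ± 2.37 and 54.6% ± 1.53, and in megakaryocyte lineage-like cells 74.8% ± 3.10 and 58.0% ± 4.67. In cluster 7 it was 60.3% ± 2.09 and 44.3% ± 4.42, and in cluster 21 48.8% ± 4.05 and 14.8% ± 3.58. In HSC-like cells it was 42.9% ± 3.01 and 36.7% ± 1.92, and in granulocyte-monocyte progenitor-like cells 75.2% ± 4.30 and 63.3% ± 3.28. Every WT sample lay above every Txnip-KO sample over all kept cells and in 10 of the 17 classes (exact permutation p = 0.1, the smallest possible, and 0.164 after Benjamini-Hochberg adjustment over 18 comparisons), so 0 comparisons passed 0.05, which this design cannot reach. In neutrophil-like cells the values were 62.0% ± 6.07 and 65.5% ± 3.07. Phase calls rest on the S and G2M lists alone, and unthinned the shares over all kept cells were 45.6% and 32.0%. They depend on depth: in NK or innate lymphoid-like cells the shares were 23.4% in WT and 19.4% in Txnip-KO thinned. Unthinned they were 9.13% and 7.97% there (exact permutation p = 0.4). In neutrophil-like cells the unthinned shares were 44.3% and 41.3%, and in HSC-like cells 38.3% and 23.3%.

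**Figure D4:**
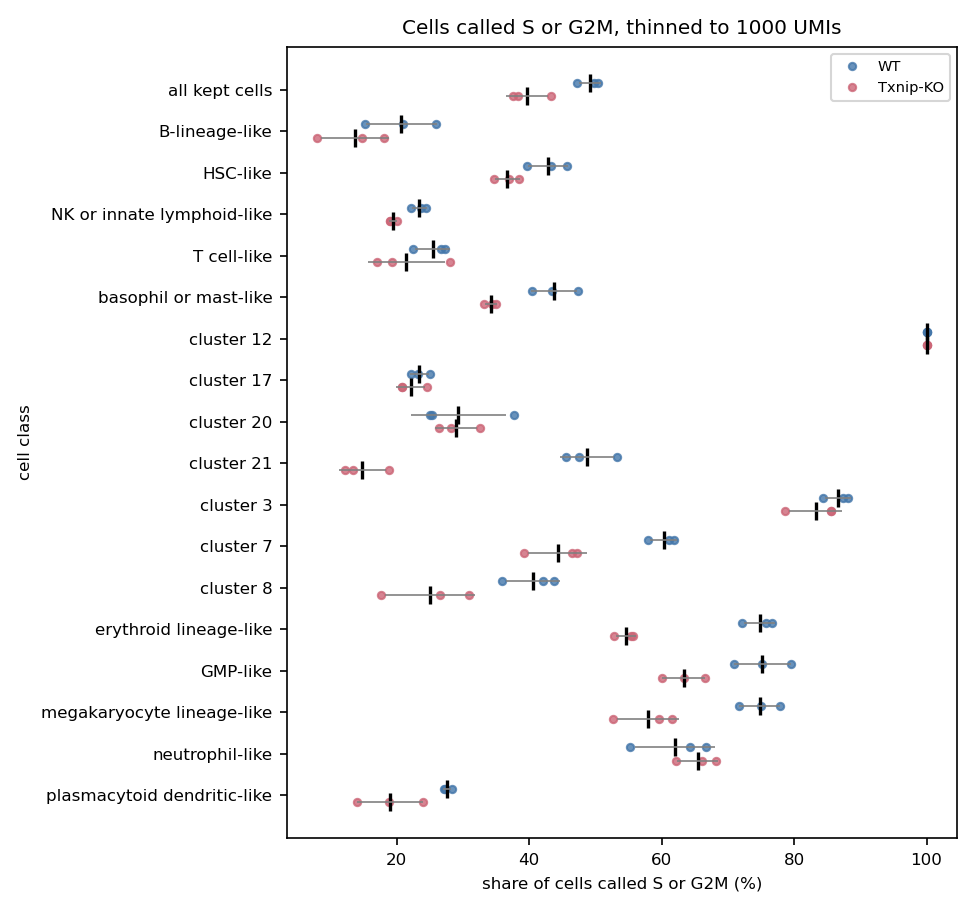
Share of cells called S or G2M in percent (x axis) after thinning each cell to 1000 UMIs, over all kept cells and in each of 17 classes (y axis). Points are samples (3 WT in blue, 3 Txnip-KO in red), black bars group means and grey lines ± SD, with 49.1% in WT and 39.7% in Txnip-KO over all kept cells.

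Class shares were compared over sorted and kept cells, so the sort and the cell filter set part of each share. HSC-like cells made up 8.68% ± 0.756 of WT and 14.2% ± 3.05 of Txnip-KO cells (log2 fold change 0.71, SE 0.24), plasmacytoid dendritic cell-like cells 8.79% ± 1.75 and 4.91% ± 1.07 (-0.84, SE 0.27). Monocyte-like cells made up 1.24% ± 1.25 and 0.0793% ± 0.104 (-4.03, SE 1.15) and stromal-like cells 0.0603% ± 0.0396 and 0.238% ± 0.0912 (1.97, SE 0.59), with n = 3 each. The monocyte-like class is cluster 18 alone, with 252 cells and 8 of 12 monocyte markers past the naming fold. The unnamed cluster 21, with 1528 cells, had 11 of 12 such markers beside 8 dendritic cell markers. It made up 4.08% ± 0.390 of WT and 3.40% ± 1.19 of Txnip-KO cells (-0.27, not called). The monocyte-like value therefore does not stand for all cells with monocyte markers. Basophil or mast-like cells made up 12.1% ± 0.850 and 6.01% ± 3.62, and erythroid lineage-like cells 10.4% ± 1.04 and 14.0% ± 3.04. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 21 shares passed 0.05 (lowest adjusted p = 0.0988). Of these 7 had an unadjusted p under 0.05, and 0 were called by the exact permutation test (lowest adjusted p = 0.21). Of these 7, clusters 3, 8 and 12 had no counterpart once clustered without the changed genes, so their shares are not compared. Genes that define some clusters changed between the groups. After clustering without the 9258 genes changed in any class, the log2 fold change was 0.69 for HSC-like (43.7% of whose cells kept the name) and -1.04 for plasmacytoid dendritic cell-like cells. It was -4.02 for monocyte-like, 2.14 for stromal-like and -1.18 for basophil or mast-like cells, again with 0 called by the edgeR quasi-likelihood test (lowest adjusted p = 0.0792). In WT 1, 2 and 3 monocyte-like cells were 2.68%, 0.584% and 0.441% of cells, and in Txnip-KO 1, 2 and 3 neutrophil-like cells were 4.52%, 0.281% and 1.42%. The basophil or mast-like fall was called without Txnip-KO 1 (-1.62, adjusted p = 0.00429), and the neutrophil-like rise without Txnip-KO 2 (2.58, adjusted p = 0.0182), both by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Without Txnip-KO 1 the neutrophil-like value was 0.79 and not called. The monocyte-like value was -2.76 without WT 1, -5.87 without Txnip-KO 1, -1.54 at resolution 2 and -0.59 without doublet removal, none of them called, and was called with the replicate number as a block (-4.11, adjusted p = 0.00113 by the same edgeR test). The HSC-like share was called higher at resolution 2 (1.18), without doublet removal (0.77) and with the stricter cell filter (1.24). At resolution 0.5, at resolution 2 and without doublet removal the plasmacytoid dendritic cell-like share was called lower (-1.24, -0.91 and -0.88), and the stromal-like share higher (2.14, 1.97 and 2.14). The B-lineage-like share was not called (0.23), but was called lower at resolutions 0.5 (-1.12) and 2 (-1.14), with genes centred per sample (-1.26), without doublet removal (-0.65) and with the stricter cell filter (-1.28). Named classes were matched across clusterings by name alone, so they hold other sets of cells there. Monocyte-like cells of WT 1, 2 and 3 numbered 166, 41 and 30 in the main clustering and 445, 429 and 388 without doublet removal. B-lineage-like cells of these samples numbered 105, 81 and 100, and 334, 356 and 389 at resolution 0.5. Such values do not show the share of a fixed set of cells changing. Without doublet removal, WT 1, 2 and 3 held 4, 9 and 11 plasma cell-like cells and Txnip-KO 1, 2 and 3 held 1, 42 and 12. With doublets removed, plasma cell-like cells were 0 of 20008 WT cells, which allows a share of up to 0.0150% over the group. They were 0.158% of all Txnip-KO cells, at least 10.5-fold higher against that floor of 3 counts, a bound that holds only with doublets removed. All 34 came from Txnip-KO 2, with 0 in Txnip-KO 1 and 3 (exact permutation p = 1), so this pooled value rests on 1 library and takes cells as units.

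The effect of genotype was set against that in NK or innate lymphoid-like cells for each of the other 16 classes. The interleukin-7 receptor Il7r rose in NK or innate lymphoid-like cells (2.07) and fell in cluster 12 (63.2 to 22.03 CPM, -1.48), a difference of -3.57 (SE 0.24). The chemokine Ccl4 fell in NK or innate lymphoid-like cells (317 to 159 CPM, -0.997) and rose in HSC-like cells (42.5 to 78.5 CPM, 0.88), a difference of 1.86 (SE 0.15). Cluster 12 is an unnamed cluster led by division genes. Ly6d and Cox6a2, leading genes of the plasmacytoid dendritic cell-like cluster 23, fell in it too. A shift in its mix of cells was not separated from a change within a cell type. In the reference class cluster 13 held 75.2% of cells in WT and 47.8% in Txnip-KO, cluster 14 20.5% and 43.1%, and cluster 27 4.24% and 9.10%. Over the 16 comparisons, 8465 differences passed 0.05 by the edgeR quasi-likelihood interaction test with Benjamini-Hochberg adjustment. They ran from 25 in T cell-like to 1088 in basophil or mast-like cells, with 449 in HSC-like cells. With a library left out these counts ran from 3 to 509, from 615 to 1569 and from 233 to 565. The order of the classes moved as well: with DESeq2 size factors basophil or mast-like cells had 1060 and cluster 21 had 1104. Il7r and Ccl4 were chosen after their values were seen, and the total dropped to 4575, 5381 and 4868 without WT 1, 2 and 3.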

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

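The tests of residual Txnip UMIs, of cell class make-up and cell cycle phase, and of the region around Txnip were chosen after the results were seen. The thinning test and the correlation of Polr3gl with Txnip were fixed before their values were seen, and a control of the thinning was added after the first thinned value but before its own.

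The genotype effect differed from that in NK or innate lymphoid-like cells, by the interaction test, in 118 genes of B-lineage-like, 449 of HSC-like, 25 of T cell-like, 1088 of basophil or mast-like, 880 of erythroid lineage-like, 666 of granulocyte-monocyte progenitor-like, 652 of megakaryocyte lineage-like, 220 of neutrophil-like and 786 of plasmacytoid dendritic cell-like cells. In clusters 3, 7, 8, 12, 17, 20 and 21 the counts were 361, 584, 1010, 357, 59, 126 and 1084. In the NK or innate lymphoid-like class cluster 13 held 75.2% of cells in WT and 47.8% in Txnip-KO, cluster 14 20.5% and 43.1%, and cluster 27 4.24% and 9.10%. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The highest of the other splits gave 28 genes in B-lineage-like, 47 in T cell-like, 7 in neutrophil-like, 5 in cluster 17, 1 in HSC-like, megakaryocyte lineage-like, cluster 12 and cluster 20 cells, and 0 in the other 8. In T cell-like cells 3 of the 10 splits gave a count of at least 25, and in the other 15 comparisons 1 did, the real one. The T cell-like count ran from 3 without WT 3 or Txnip-KO 1 to 509 without WT 2.

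Ccl4 differed by 1.86 in HSC-like cells, with 0.88 against -0.997 in NK or innate lymphoid-like cells. Il7r differed by -3.57 in cluster 12, with -1.48 against 2.07, and the mix of cells in this unnamed cluster of dividing cells was not separated from it. Gpr183 differed by -2.30 in plasmacytoid dendritic cell-like cells, with -0.61 against 1.75. Ms4a6c differed by -1.98 in granulocyte-monocyte progenitor-like cells, with -0.92 against 1.10. These 4 genes were chosen after their values were seen.

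Txnip UMIs remained in Txnip-KO 1 and 2 (584 and 662, against 28 in Txnip-KO 3). Wild-type cells mixed in would hold several Txnip UMIs each, but 1.93% of the 1089 positive cells held at least 3 (upper 95% limit 2.93%, exact Clopper-Pearson), against at least 43.0% in the WT samples, which argues against such cells. Free RNA caught in droplets would give all classes a like level, per cell or per UMI. Txnip UMIs per cell differed 3.17-fold between the classes with at least 20 of them. They ran from 52.1 per 1000 plasmacytoid dendritic cell-like cells to 165 per 1000 cells of cluster 12, with 43 UMIs. That contrast goes with depth, as scaled by total UMIs these classes had 7.52 and 8.17 CPM. Other classes differed on that scale too. Erythroid lineage-like cells had 4.23 CPM (104 Txnip UMIs) and HSC-like cells 15.9 CPM (323 Txnip UMIs, 146 per 1000 cells). A chi-square test of the Txnip UMIs over all 17 classes gave p = 1.73e-53 with expectations by UMIs and 5.63e-40 by cells. These values argue against free RNA as the whole source of the Txnip UMIs. Transcription left in the knockout cells may account for them. Over 17 classes of the same samples the residual level and the WT level had a Spearman correlation of 0.272 (permutation p = 0.290). The Pearson correlation was 0.230 (permutation p = 0.297). The same chi-square test with expectations by the WT Txnip level gave p = 1.26e-125, which argues against a residual in proportion to that level. Neutrophil-like cells had the highest residual, 35.3 CPM, on 40 Txnip UMIs, 38 of them in Txnip-KO 1. Transcription that does not follow the WT level stays open. A difference between the animals or in the deletion was not tested, since the labels do not describe it.

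The breadth of the change over all kept cells (6010 genes) may be biological or may stem from cell make-up, phase or depth. With the same number of cells of each class 85.1% of these genes stayed called in the same direction, and with cells called G1 alone 64.5% did. Neither class make-up nor phase as called here accounts for the whole. Both were evened only in part. Classes were matched as joined, so shifts between the clusters of a class were left in. Among cells called G1, S genes were still lower by limma's camera at the preset correlation (adjusted p = 5.37e-05). With each cell thinned to 1000 UMIs 41.1% stayed called, below the bound of 50% set beforehand, but that kept 10.7% of the UMIs, and sums thinned to the same totals without evening the cells kept 55.6%. The number kept with cells evened was 0.739 of that control, so the lower number of UMIs per Txnip-KO cell does not by itself account for the whole. Thinning evens that number only. It leaves in any difference between the libraries that acts on some genes more than on others, which was not tested. Evening the cells ended more calls than the loss of counts alone. It also gave every cell the same weight, and these effects were not separated. The labels name no batch or handling difference, and one that followed genotype could not be tested here. The knockout itself stays open as well.

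Polr3gl, next to Txnip, rose by 1.92 over all kept cells. A change of the whole region of 1 Mb is argued against by the other 53 tested genes within 1 Mb, whose median log2 fold change was 0.09, although 27 of all 54 were called (41.0% of all genes were). The nearest genes were higher as well, with Gm16253 at 2.31 (15101 bp away), Lix1l at 0.98 (39266 bp) and Gm15441 at 1.72 (not called), and Gm15444 (2.45) and Ciart (2.005) were above Polr3gl. A change limited to the nearest genes was not tested and stays open. Transcripts started at the Txnip promoter would run against the strand of Polr3gl. They could add to Polr3gl counts only if counting ignored strand. Over 16 classes the gain of Polr3gl and the WT Txnip level had a Spearman correlation of 0.797 (permutation p = 0.00029). The Pearson correlation was 0.704 (permutation p = 0.00839). Without the 2 farthest classes the Spearman and Pearson values were 0.719 and 0.556. The genes lie on opposite strands, the classes come from the same 6 samples, and whether counting used strand is not known here, so this stays open. A loss of Txnip acting on Polr3gl through the cell was not tested.

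For the counts of changed genes, the 10 splits are likewise too few for a share under 0.05, and 1 of the 10 gave a count as large in each case, the real one. Over all kept cells the real split gave 6010 genes and the highest other 0. The real and highest other counts were 325 and 1 (B-lineage-like), 76 and 19 (T cell-like), 240 and 1 (cluster 17) and 86 and 6 (cluster 20), and the highest other was 0 in the other 13 classes, where the real counts ran from 72 (neutrophil-like) to 4559 (granulocyte-monocyte progenitor-like). Camera with the preset correlation called 15 lists on the real split and 14 on the highest other, and class shares gave 0 and 0, so that all 10 splits gave as many.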

How the results depend on the processing

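Cells called G1, cells thinned to 1000 UMIs before the sums, clustering without changed genes and single clusters of a class were alternatives chosen after the data were seen, and the others before. Each library left out gave 135 of 144 values of the named genes over all kept cells on the same side of the threshold and 9 past it no more, and the other settings 232 and 7 of 239. For class genes the values were 1034 and 88 of 1122 with a library left out, and 1255 the same, 40 weaker and 4 reversed of 1299 otherwise. Lists kept 201 of 204 calls and non-calls with a library left out. Under the block, equal classes, G1 cells or an estimated correlation 114 of 136 did, 20 were weaker and 2 stronger. Class shares kept 119 of 125 (2 stronger, 4 reversed) and 143 of 162 (12 stronger, 7 reversed), and cycling shares 98 of 102 and 14 of 17, the others reversed. The cause of the changes listed here was not tested unless stated. In simulated T cell-like counts, the only small class simulated, 48.3% of changes of 1 on the log2 scale were recovered.

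With a library left out, the changed genes ran from 3609 to 6148 over all kept cells, 147 to 347 in B-lineage-like, 2517 to 4159 in HSC-like, 1758 to 3014 in NK or innate lymphoid-like, 2 to 387 in T cell-like, 479 to 2527 in basophil or mast-like, 2290 to 4474 in erythroid lineage-like, 2044 to 3650 in megakaryocyte lineage-like and 36 to 154 in neutrophil-like cells, and 40 to 286 in cluster 17, 25 to 110 in cluster 20 and 1274 to 1821 in cluster 3. Called shares ran from 0 to 1. Differences from NK or innate lymphoid-like cells ran from 4575 to 8674 in all, 31 to 239 in B-lineage-like, 233 to 565 in HSC-like, 3 to 509 in T cell-like, 615 to 1569 in basophil or mast-like, 438 to 1068 in erythroid lineage-like, 283 to 1154 in granulocyte-monocyte progenitor-like, 284 to 748 in megakaryocyte lineage-like, 74 to 454 in neutrophil-like and 421 to 765 in plasmacytoid dendritic cell-like cells, and 160 to 497, 251 to 689, 536 to 1314, 100 to 417, 23 to 96 and 22 to 191 in clusters 3, 7, 8, 12, 17 and 20. The log2 change of the share ran from -0.15 to 0.64 (B-lineage-like), -0.31 to 0.053 (share of cluster 20) and -0.11 to 0.16 (cluster 7), and the difference in cycling cells in cluster 20 from -2.47 to 3.87 points and from -0.0198 to 5.73 in neutrophil-like cells.

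With each cell thinned to 1000 UMIs 2647 genes changed over all kept cells, with fewer counts by construction. By the Wald test 104 changed in B-lineage-like cells, 138 in cluster 17, 1127 in cluster 3 and 42 in neutrophil-like cells. Without the filter on low counts 247 changed in T cell-like cells, 397 in cluster 17, 253 in cluster 20 and 153 in neutrophil-like cells. Without doublet removal 3387 changed in B-lineage-like and 244 in T cell-like cells, 112 in cluster 17, 204 in cluster 20 and 150 in neutrophil-like cells, and 5 shares were called, 1 of them that of cells matched to no class. The stricter cell filter gave 531 in B-lineage-like and 2050 in megakaryocyte lineage-like cells and 2 shares. At resolution 0.5, 1144 changed in B-lineage-like cells and 465 in cluster 17, and 3 shares were called. At resolution 2, 1030 changed in B-lineage-like, 2373 in HSC-like, 1754 in granulocyte-monocyte progenitor-like cells and 1757 in cluster 21, and 6 shares were called. Genes centred per sample gave 1 called share. Named classes were matched across clusterings by name alone, so their cells differ between these settings. The share change of B-lineage-like cells turned from 0.23, not called, to called falls of -1.12 (resolution 0.5), -1.14 (resolution 2), -1.26 (genes centred), -0.65 (no doublet removal) and -1.28 (stricter filter), that of granulocyte-monocyte progenitor-like cells from 0.45 to -0.70 (called) and that of cluster 21 to 0.0021 at resolution 2. The HSC-like share was called at resolution 2 (1.18), without doublet removal (0.77) and with the stricter filter (1.24). With an estimated correlation camera called 0 lists. Unthinned, the cycling difference turned to 0.890 points in cluster 17, 2.39 in cluster 20 and -3.03 in neutrophil-like cells. In erythroid lineage-like cells Hba-a1 turned to -0.34 without doublet removal and -0.38 at resolution 0.5, and Hba-a2 to -0.24 and -0.35. DESeq2 size factors gave 2941 higher and 3067 lower genes over all kept cells and 8178 differences between classes.

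Samples with the same number in both groups deviated together with correlations of 0.0811, 0.108 and 0.0635 over genes, so the numbers were not taken to pair the samples, although every sample correlated best with its own number, a hint from the data. With the replicate number as a block 6483 genes changed over all kept cells, 14 in T cell-like cells, 143 in cluster 17 and 124 in neutrophil-like cells. Igkc lost its call (2.15), and 2 shares were called, monocyte-like (-4.11) and plasma cell-like. The block changed no list's call.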

Other observations

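The choice of genes below, by how many classes called them, was made after the data were seen.

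Some genes changed across nearly all cell types. Lars2 and Txnip were lower in all 17 tested classes, Lars2 by between -2.85 and -1.70 on the log2 scale, and Zfp36l2, which binds AU-rich elements of mRNA, was higher in all 17 (0.48 to 1.51). Klf10 was higher in 16 of the 16 classes where it was tested (1.43 to 4.79), and Arrdc4 in 15 of 15 (1.25 to 4.11). Tsc22d3, a glucocorticoid-induced gene, was higher in 16 of 17 classes (median 1.63), and so were the nuclear RNA Malat1 (0.59) and mt-Co1 (0.54). Neat1 (1.24) and Ogt (0.80), the enzyme that adds N-acetylglucosamine to proteins, were higher in 15 of 17. Actb (-0.68) and Rpl27 (-0.75) were lower in 16 of 17, the actin-binding Pfn1 (-0.71) in 15, and the chaperone Hspa5 (-0.62) and the mitochondrial pyruvate carrier Mpc1 (-0.81) in 14 of 17. Oxct1 was lower in 13 of 14 (median -2.13). In all, 130 genes were higher and 202 lower in at least 12 classes, while 751 of the 9258 genes called in any class were called higher in some and lower in others.

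Txnip-KO cells held fewer UMIs in 15 of the 17 classes. The mean of sample medians was 14942 ± 582 and 10419 ± 1061 in granulocyte-monocyte progenitor-like cells and 10897 ± 193 and 8318 ± 1041 in HSC-like cells (WT and Txnip-KO, SD, n = 3), ratios of 0.697 and 0.763. The ratio was 1.06 in T cell-like and 1.24 in basophil or mast-like cells. In basophil or mast-like cells it rests on Txnip-KO 3 (4629), as Txnip-KO 1 and 2 (2131 and 1773) lay below every WT sample (2326, 2362 and 2206). Cluster 15 had a median of 2004 and cluster 16 of 8835, and Txnip-KO 3 held 151 and 148 cells of them, so the ratio goes with the mix of clusters. T cell-like cells also shifted between clusters 22 (5255) and 24 (3658). No test of these medians was run.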
